A study of Rattus norvegicus with 20 samples.

How the data were processed

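The series holds 20 two-colour Agilent CpG island arrays, 1 per tissue sample: 4 normal mammary glands and 16 mammary carcinomas of female rats, grouped by their titles. Per the labels, Cy5 carried DNA isolated with a methyl-CpG-binding domain protein and Cy3 carried input DNA of the same tissue, with the same dyes on all arrays. For carcinomas 7 and 8 the sample code in the description differs from the code in the name of the scanner file, so which of the tumours these are is uncertain, and each file was used under the sample it was deposited with. The labels number the samples without naming animals, so p-values measure the spread between samples.

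Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.3.1 and carry probe coordinates of build rn4. The deposited processed signals are intensities that were background-subtracted and dye-normalized with a linear factor per channel, and the lowess factor in the headers was 0. The deposited log ratio of the scanner files is the log10 of Cy5 over Cy3 per the file headers. The authors' value table holds 91897 of 93024 probes as log2 ratios: each value equalled the scanner log ratio rescaled to log2, to within 7.94e-07. Its column medians ran from -0.48 to -0.08, so it was not centred, and it was used as an alternative.

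Here, log2 of the processed Cy5 over the processed Cy3 signal was taken for each probe, and the 1565 control spots were left out. The 187 values that the scanner software had marked as non-uniform or as population outliers were set to missing. The 91599 probes with input well above background on at least 10 arrays were kept, and each array was centred on its median. No loess or quantile step was applied, since many islands may shift the same way. A region was a run of probes starting at most 500 bases apart, with at least 3 probes and the mean as its value; 13556 of 16436 runs met this. Centring makes each log2 value relative to the median of its array, so a shift shared by all regions cannot be seen.

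Groups were compared with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over regions and a call at an adjusted p under 0.05. Single values per array were compared with two-sided exact permutation tests over all 4845 splits into 4 and 16. Regions named as the largest changes were the 5 with the largest rise and the 5 with the largest fall in log2 ratio past the threshold. This rule, the region test, and the tests of chromosomes, spread and input signal per chromosome were fixed before the data were examined, and the closing part says which alternatives were added later. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and version 1.17.8 of data.table.

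Linear position was added after the data were examined. On each array the density mode of all regions was set to 0 and the mode of the highest 15% of regions to 1, on the unlogged ratio. The region test was tested on simulated data over 13556 regions: of 50 regions changed by each size, it recovered 38% at a log2 change of 0.5, 56% at 1, 94% at 1.5 and 100% at 2, and called 3 of 13356 unchanged regions. The simulated noise was independent between regions and arrays, with the same SD in both groups. The 3 false calls therefore do not cover structure shared between arrays. In simulated arrays with the ranges of the real ones, regions of mean methylation 0.498 had mean linear positions between 0.488 and 0.526, while their mean log positions ran from 0.648 to 0.779 with the range of the array. The ratios were simulated as linear in methylation, the relation that linear position inverts, so this outcome followed from the setup. It does not test whether enrichment on the real arrays is linear.

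Input signal was log2 of the processed Cy3 signal, averaged per chromosome or per window of 5 megabases with at least 10 probes (529 windows), minus the mean of the normal glands; a normal gland was set against the other normal glands. Scan days and slides came from the file headers. Scan day 1 held 2 carcinomas, scan day 2 held 2 normal glands and 6 carcinomas, and scan day 3 held 2 normal glands and 8 carcinomas. None of the 10 slides held both groups, so slide entered as a random block (consensus correlation -0.11).

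Alternatives covered the normalization, background correction, source of values, filter on dim probes, region size, threshold, array weights, scan day, slide, replicate number and each array left out. Tests of genes, gene lists and probe classes were planned. They were not run, because the files give no gene names or probe sequences and the gene table at hand is of another build. Corrections for GC content were not run for the same reason. Normexp used median signals, since mean signals were not among the columns used here.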

Results

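DNA methylation was profiled over CpG islands of the rat genome in 4 normal mammary glands and 16 mammary carcinomas from female F1 hybrids of the Sprague-Dawley and Copenhagen strains. The labels put 4 Gy of whole-body gamma rays, given at 0.5 Gy per minute at 7 weeks of age, among the treatments, and the series title calls the carcinomas radiation-induced. Whether the normal glands came from irradiated or untreated rats is not given in the sources used here, so a difference between the groups can also hold an effect of irradiation. On each array, DNA pulled down with a methyl-CpG-binding protein domain was labelled with Cy5, and input DNA of the same tissue with Cy3. A high log2 ratio of Cy5 to Cy3 therefore marks a region rich in methylated CpG. After filtering, 91599 probes formed 13556 regions of at least 3 neighbouring probes, with a median of 6 probes and 579 bases. All coordinates are those of build rn4. The median raw Cy5 signal lay between 63 and 130 units and the median raw Cy3 signal between 74 and 138. Input signal was well above background for between 92.9% and 100% of probes per array, and enriched signal for between 70.0% and 98.5%. The number of arrays limits the precision of each comparison, above all the 4 normal glands.

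The first comparison asked which CpG island regions differed in methyl-CpG enrichment between carcinoma and normal gland. On every array a low mode was taken from all regions and a high mode from the 15% of regions with the highest ratios. The regions around them are called the low and the high group here. Whether these are separate groups was not tested. The high group stood far lower in the carcinomas: its mode was 4.68 ± 0.82 (SD, n = 4) on the log2 scale in normal glands and 2.72 ± 0.49 (SD, n = 16) in carcinomas (two-sided exact permutation test over 4845 splits, p = 0.0002064, the smallest the design allows). With limma and Benjamini-Hochberg adjustment, 1576 regions were higher and 3216 were lower in carcinomas at an adjusted p under 0.05. Nearly all regions with the highest ratios were lower. Of the 1249 regions whose mean over all 20 arrays lay over 0.8 of the range between the modes of the low and the high group, 1215 were lower and 0 were higher, with a median difference of -1.94. Of 9799 regions with such a mean under 0.2, 1303 were higher and 1124 were lower. After loess within each array there were 1301 higher and 1447 lower regions, and after normexp background correction 471 and 2916, so that lower calls made up 52.7% and 86.1% of calls in place of 67.1%.

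Because the carcinoma arrays spanned a narrower range, each region was also placed within the range of its own array, with 0 at the mode of the low group and 1 at the mode of the high group on the linear scale. This linear position was chosen after the log2 ratios had been seen. On it the balance turned: 2345 regions were higher and 589 were lower, so that lower calls made up 20.1% of calls. Of the higher calls, 1729 (73.7%) had a mean under 0.2 in normal glands, which was also the most common level, as 11031 of all 13556 regions were under 0.2 in every normal gland. In the median such higher call, 1 of the 16 carcinomas was over 0.5. Over all higher calls the median of the group means was 0.0645 in normal glands and 0.425 in carcinomas. Of the 589 lower calls, 234 had a mean over 0.2 in normal glands. The rest already lay in the low part of the range there, so most lower calls were not falls from a high level. Of the 1249 regions with a mean over 0.8, 1215 of which were lower in log2 ratio, 299 were higher and 166 were lower in linear position, with a median difference of 0.0148. Of 338 X regions, 72 were higher and 32 were lower. On a log scale between the same modes, which shifted with the range of the array in the simulated arrays, there were 1928 higher and 573 lower regions (22.9% lower). With percentiles of the regions in place of the modes there were 3059 and 356 (10.4% lower). The calls shared by both measures were 498 higher and 268 lower regions, while 535 regions were lower in log2 ratio and higher in linear position. Over the 8 scales and corrections run, 210 regions were higher in each and 45 were lower in each. Without normal gland 1, the higher calls fell to 891 in log2 ratio and 945 in linear position. Without normal gland 3 they were 976 and 1145, and without normal gland 4 the linear position gave 1164. Lower calls in linear position were 164, 315, 240 and 243 without normal glands 1, 2, 3 and 4 in turn. With scan day as a block, the log2 ratio gave 1417 higher and 3129 lower regions. Within scan day 2 it gave 609 higher and 2263 lower, and within scan day 3, 292 higher and 2393 lower. The linear position gave 2868 higher and 697 lower with the block, 372 and 14 within scan day 2, and 462 and 110 within scan day 3.

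**Figure D1:**
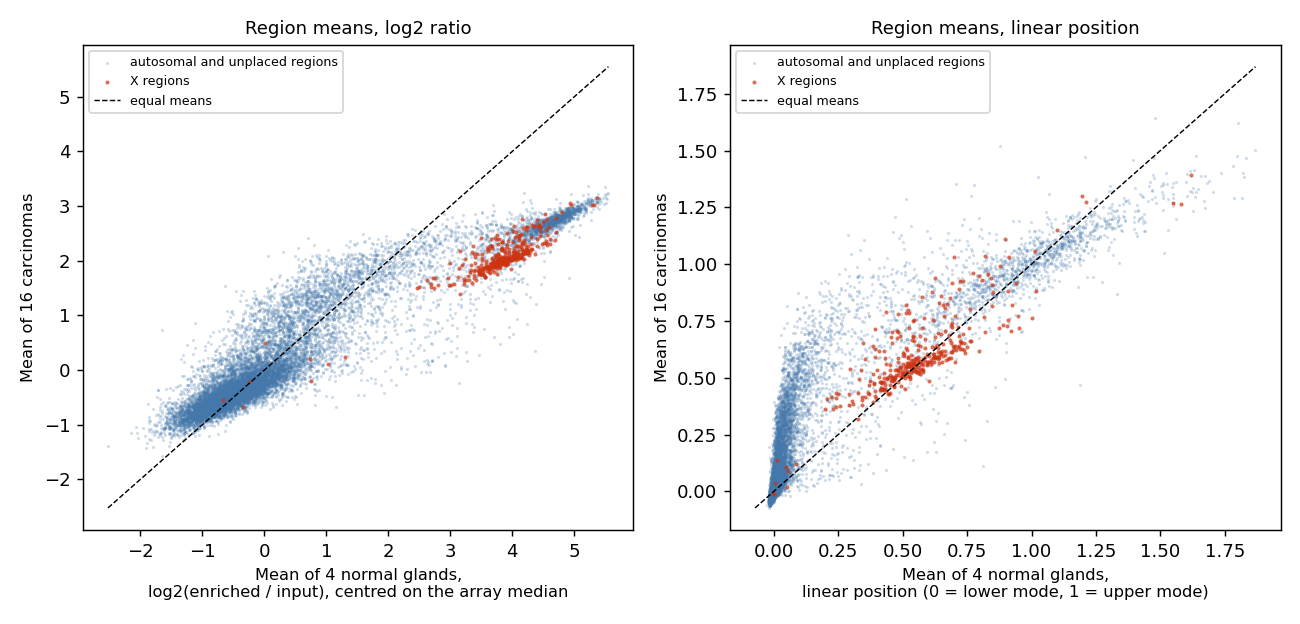
Each point is a region, with its mean over the 4 normal glands on the horizontal axis and over the 16 carcinomas on the vertical axis, as log2 ratio (left) and linear position (right); X regions are red and the dashed line marks equal means. The most enriched regions fell below the line in log2 ratio by a median of 1.94, while in linear position 2345 regions were higher and 589 lower in carcinomas.

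The region with the largest fall in log2 ratio lay on chromosome 2 from 175940970 to 175941737. Its 10 probes averaged 4.37 ± 0.85 (SD, n = 4) in normal glands and 0.34 ± 0.58 (SD, n = 16) in carcinomas, a difference of -4.02 (SE 0.33, limma adjusted p = 8.04e-08), and all 16 carcinomas lay below every normal gland. Its linear position went from 0.811 to 0.113, also lower in 16 of 16 carcinomas. The next largest falls were on chromosome 1 from 95950255 to 95950677, with a difference of -3.39, on chromosome 1 from 187510308 to 187510888 with -3.37, on chromosome 18 from 71365517 to 71366000 with -3.35, and on chromosome 20 from 19290912 to 19291405 with -3.34. Each of these was below every normal gland in 16 of 16 carcinomas and was also lower in linear position at an adjusted p of at most 0.0025. Such full separation in log2 ratio was common, as 2115 of the 3216 lower regions had it. After loess normalization the 5 differences were -1.54, -0.42, -1.48, -1.47 and -1.29 in the order named, and the one on chromosome 1 from 95950255 no longer passed, with an adjusted p of 0.322.

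The largest rise in log2 ratio was on chromosome 18 from 60545867 to 60546266, from -1.65 ± 0.21 (SD, n = 4) to 0.73 ± 0.92 (SD, n = 16), a difference of 2.38 (SE 0.44, limma adjusted p = 0.000152). Of its 5 probes, 2 had enriched signal well above background on any normal array, and in linear position the adjusted p was 0.0868. Its normal value is therefore poorly measured, and its place as the largest rise holds for the log2 ratio after median centring. After normexp background correction it rose by 0.52, and the regions named next, on chromosomes 3, 10, 5 and 11, by 0.76, 1.18, 0.44 and 0.69 in turn. A region on chromosome 3 from 91133568 to 91134109 rose by 2.18 (SE 0.29), from -0.63 ± 0.74 (SD, n = 4) to 1.54 ± 0.51 (SD, n = 16), with a limma adjusted p of 1.95e-05. A region on chromosome 10 from 18097053 to 18097347 rose by 2.02, from a linear position of 0.0198 to 0.635. The others were on chromosome 5 from 142598928 to 142599126, which rose by 1.97 with 3 of its 4 probes well above background in Cy5 on any normal array, and on chromosome 11 from 31203594 to 31203946, which rose by 1.90. In log2 ratio all 16 carcinomas were above every normal gland in each of these 5 regions, and the last 4 were also higher in linear position.

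The share of regions in the upper part of the array range, with a linear position over 0.5, described each tissue in a single value. It was 12.2% ± 0.680 (SD, n = 4) in normal glands and 18.4% ± 3.64 (SD, n = 16) in carcinomas, a difference of 6.19 percentage points (two-sided exact permutation p = 0.00372). Normal glands ranged from 11.5% to 13.0%, and carcinomas from 12.9% in carcinoma 3 to 25.4% in carcinoma 15. Within scan day 2 the difference was 7.61 points (exact permutation p = 0.0714) and within scan day 3 it was 6.18 points (exact permutation p = 0.0444); on both days every carcinoma lay above both normal glands. Of 11031 regions under 0.2 in every normal gland, a median of 2.78% had passed 0.5 in a carcinoma, with a range from 0.127% in carcinoma 2 to 11.0% in carcinoma 15. Of 1455 regions over 0.5 in every normal gland, a median of 0.378% were under 0.2 in a carcinoma, and the highest share was 1.65%. In 255 regions all 4 normal glands were under 0.2 and at least 8 carcinomas were over 0.5. The opposite held for 3 regions. On the carcinoma arrays, with their narrower range, a position of 0.5 stood at a lower log2 ratio than on the normal arrays. A region could thus pass 0.5 without a rise in log2 ratio, and 535 regions were lower in log2 ratio and higher in linear position. Both contrasts between rises and falls therefore depend in part on the measure.

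**Figure D2:**
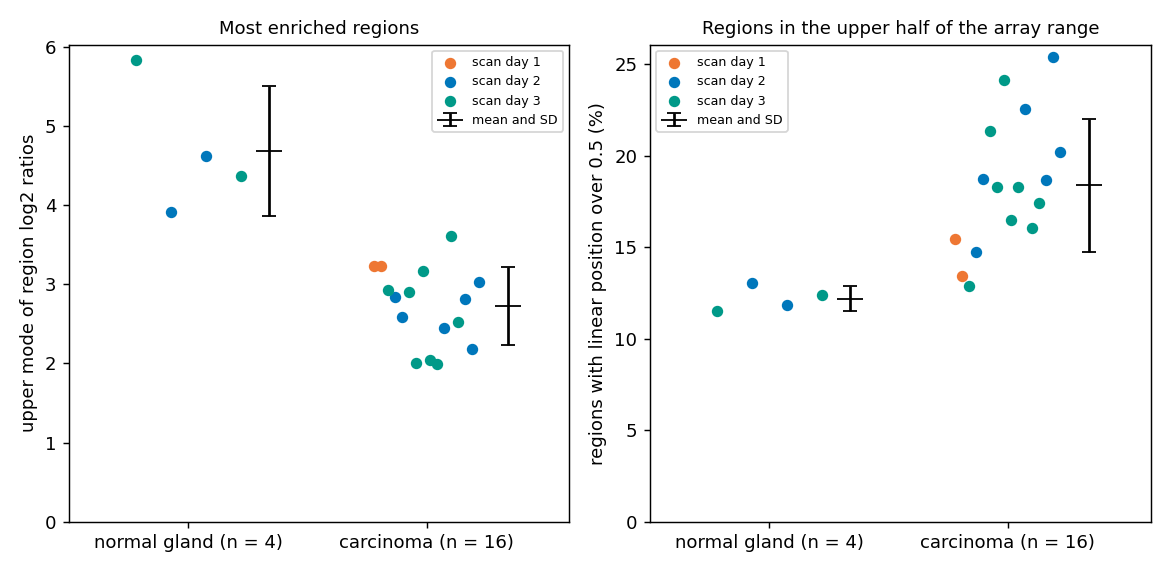
Each point is an array, coloured by scan day, with group means and SD beside them; the left axis gives the mode of the most enriched regions as log2 ratio and the right axis the percent of regions with a linear position over 0.5. Carcinomas lay at 1.99 to 3.61 in the left plot against 3.91 to 5.84 in normal glands, and at 12.9% to 25.4% in the right plot against 11.5% to 13.0%.

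The next comparison asked on which chromosomes the enrichment differed. The X chromosome had the largest difference: its mean log2 ratio was 3.75 ± 0.74 (SD, n = 4) in normal glands and 2.05 ± 0.42 (SD, n = 16) in carcinomas, a difference of -1.71 with 16 of 16 carcinomas below every normal gland (exact permutation, adjusted p = 0.000867). Of 338 X regions, 331 were lower in log2 ratio, with a median difference of -1.79. The 1249 regions with a mean linear position over 0.8, on any chromosome, had a median difference of -1.94. The fall on X was therefore of the size seen in the regions of highest position. The mean position of X itself lay lower, between 0.2 and 0.8. The 2508 regions with a mean in that band, X included, had a median difference of -0.14, with 877 lower and 273 higher. Of them 1307 were higher in linear position. Whether the fall was particular to X thus depends on the regions it is set against and was not settled. Chromosomes 7, 9, 10, 11, 12, 13, 16, 18, 19 and 20 were also lower at an adjusted p under 0.05 over 21 chromosomes, by at most 0.36 on the log2 scale, as for chromosome 12 with its difference of -0.36. In linear position all 21 chromosomes were higher in carcinomas, from 0.0394 on X to 0.0800 on chromosome 3. The mean linear position of X was 0.564 ± 0.0176 (SD, n = 4) in normal glands and 0.603 ± 0.0301 (SD, n = 16) in carcinomas (exact permutation, adjusted p = 0.0233), higher than in every normal gland in 10 of 16. After quantile normalization 6 chromosomes were lower and 3 higher, and after scaling by the median absolute deviation 6 were lower. Without normal gland 1, 6 chromosomes passed in log2 ratio in place of 11. Within scan day 2 the X difference in log2 ratio was -1.41 (exact permutation p = 0.0357) and within scan day 3 it was -2.12 (exact permutation p = 0.0222), the smallest values those days allow.

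A further comparison asked whether the carcinomas differed among themselves more than the normal glands did. The mean of 1 minus the Pearson correlation over pairs was 0.0229 among normal glands and 0.0778 among carcinomas, a difference of 0.0549 (two-sided exact permutation p = 0.00846). Pairs of normal glands correlated between 0.966 and 0.987 over regions, pairs of carcinomas between 0.812 and 0.964. The difference was 0.0644 within scan day 2 (exact permutation p = 0.0714) and 0.0463 within scan day 3 (exact permutation p = 0.267). On each of these days the 2 normal glands shared a slide, while the carcinomas lay on several slides. The exact tests do not take slides into account, so a part played by the slide was not separated from group. Without normal gland 3 it was 0.0514 (exact permutation p = 0.0506), and in the settings added after the data had been seen it was 0.0502 after loess (exact permutation p = 0.0545) and 0.0578 in linear position (exact permutation p = 0.0557). As the median SD over regions, an alternative fixed beforehand, the spread was 0.259 in normal glands and 0.319 in carcinomas (exact permutation p = 0.511). In linear position, added later, this SD was 0.00773 and 0.0329 (exact permutation p = 0.0002064). Linear position divides by the range of the array, which was narrower in carcinomas. A narrower range by itself enlarges this SD, so the last value is not evidence of more spread.

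The input channel holds DNA that was not enriched, and its signal along the chromosomes was compared by itself, without a correction for GC content. The SD over autosomes of the mean log2 input signal, relative to the normal glands, was 0.0104 ± 0.00286 (n = 4) in normal glands and 0.0740 ± 0.0635 (n = 16) in carcinomas, a difference of 0.0637 (two-sided exact permutation p = 0.0452). Every carcinoma was above every normal gland, with 0.0183 as the lowest carcinoma and 0.0139 as the highest normal gland. Over windows of 5 megabases, which were added after the data had been seen, the difference was 0.0979 (exact permutation p = 0.00599). This window value was not checked against dim input signal. For both values the reference was made of normal glands only and was not rebuilt for each split. A shift in input signal shared by the carcinoma arrays would therefore raise the values of carcinomas alone. The p-values and the full separation thus do not show by themselves that the signal of single carcinomas is more uneven. The chromosome value lost its call without any single normal gland (exact permutation p from 0.0805 to 0.0867) and without carcinoma 8, 11, 14, 15 or 16 (exact permutation p from 0.0552 to 0.0661). It was 0.0812 within scan day 2 (exact permutation p = 0.0357) and 0.0617 within scan day 3 (exact permutation p = 0.222).

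Runs of at least 3 neighbouring windows beyond 0.25 on the log2 scale, a rule set after the windows had been seen, were found in 10 of 16 carcinomas and in 0 of 4 normal glands, with 34 runs lower and 4 higher. Chromosome 5 from 150000001 to 175000000 was lower in carcinomas 8, 11, 15 and 16, and in carcinoma 11 the run covered 175 megabases of the chromosome with a mean of -0.49. Chromosome 2 from 35000001 to 50000000 was lower in carcinomas 5, 7, 9 and 15. Runs on chromosome 3 were lower in 3 carcinomas, from 60000001 to 145000000 in carcinoma 8 (mean -0.53), from 60000001 to 140000000 in carcinoma 11 (-0.50) and from 55000001 to 135000000 in carcinoma 16 (-0.42). Carcinoma 3 was lower over chromosome 9 from 1 to 115000000 (-0.53), over chromosome 15 from 1 to 110000000 (-0.63) and over most of chromosomes 6 and 17. A window on chromosome 8 from 10000001 to 15000000 was higher by 1.62 in carcinoma 15, and neighbouring windows on chromosome 9 were higher in carcinoma 14, from 5000001 to 10000000 by 1.29 and from 10000001 to 15000000 by 0.99. The lowest window lay on chromosome 4 from 10000001 to 15000000 in carcinomas 1 (-0.89), 2 (-0.78) and 10 (-0.29). In carcinomas 4 (-0.80) and 5 (-0.61) it lay on chromosome 4 from 35000001 to 40000000. Each of these arrays had a median raw input signal below 105, that of the dimmest normal gland. The lowest windows of the other carcinomas lay on other chromosomes. Whether dim signal lowered the windows on chromosome 4 was not tested.

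**Figure D3:**
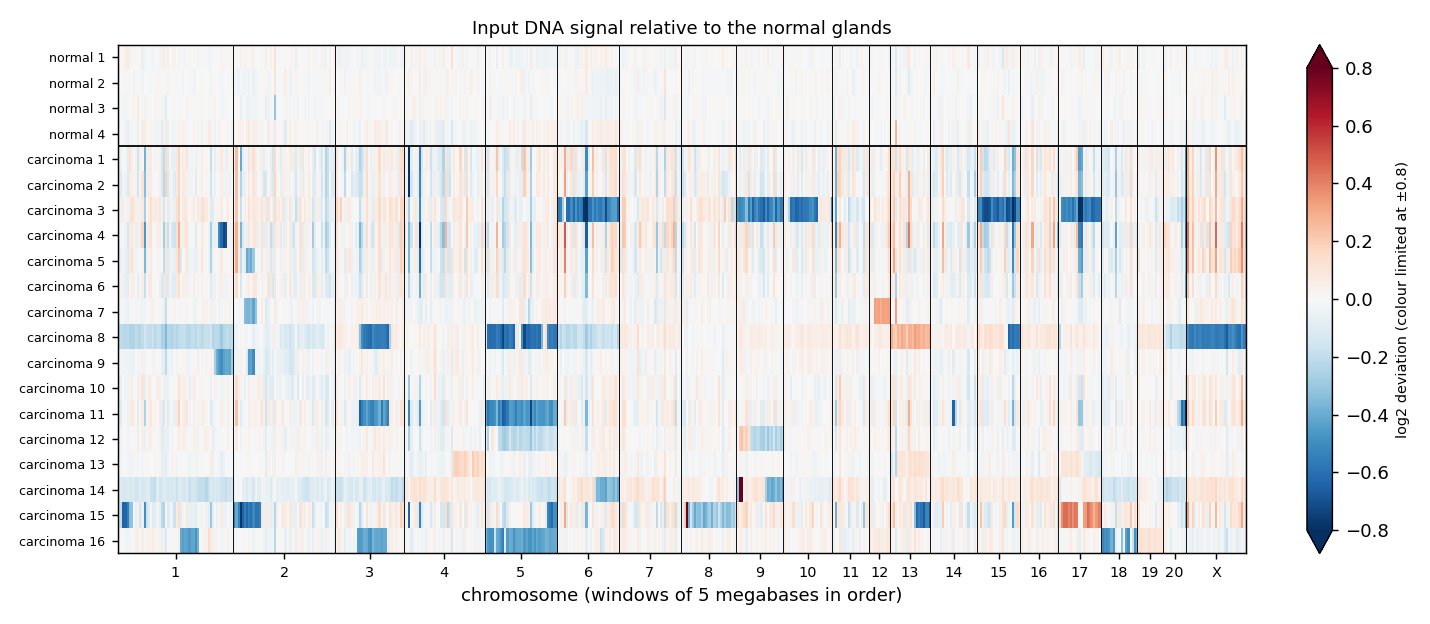
Rows of the image are the 20 arrays and columns are windows of 5 megabases in chromosome order; colour gives the log2 input signal relative to the normal glands, blue for lower and red for higher. Carcinomas carried 34 lower and 4 higher runs of windows, including chromosome 5 in carcinomas 8, 11 and 16, and the normal glands carried 0.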

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

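The tests of explanations in this part were all chosen after the patterns had been seen. Among the 4 normal glands, 67 sets of values were searched for a gland far from the other 3, and chance alone is expected to mark about 5% of such sets. Normal gland 1 stood apart in the mode of its low group, at -0.68 against -0.44 to -0.41 in the others. It also had the highest mean log2 ratio of chromosomes 1 (0.58), 3 (0.59), 4 (0.46), 5 (0.52), 6 (0.53), 8 (0.40), 9 (0.49), 10 (0.40), 13 (0.30) and 16 (0.73). These chromosome values come from a single array and are not independent of each other. Normal gland 4 stood apart in linear position in a region on chromosome 1 from 95950255, at 1.05 against 0.621 to 0.659, and in a region on chromosome 18 from 71365517, at 0.866 against 0.530 to 0.568.

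Scan day alone did not account for the lower log2 ratio of the most enriched regions in carcinomas: on each day with both groups the lowest normal gland lay above the highest carcinoma, by at least 0.753. A weaker separation of enriched from other DNA on the carcinoma arrays may account for much of it. It would lower the log2 ratio of all enriched regions alike and leave their linear position in place, and the median linear position of X regions differed by 0.0306 (exact permutation p = 0.0374, n = 4 and 16) while their log2 ratio differed by -1.80. An even, proportional loss of methylation in the carcinomas would look the same, so the technical and the biological explanation stay open. No slide held both groups and no spiked DNA was used here.

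Scan day alone did not account for the larger share of regions in the upper part of the range either, as 0 carcinomas lay at or below the highest normal gland of their day. A bent scale was tested by rank, since a monotone bend of region values keeps the order of regions on an array. A bend of probe values need not keep it, as a region is a mean over probes. Of the autosomal regions low in the other normal glands, 0 lay above the X median on each normal array. On the carcinoma arrays 9 to 969 did, more than on any normal array in 16 of 16. Noise of single probes would also raise such counts, so regions above the X median by every other probe were read by their remaining probes, and a median of 70.7% over carcinomas (45.5% to 87.7%) lay above it again, against at most 8.90% of all regions low in normal glands. These tests leave open a bend of probe values. They also leave open noise shared by neighbouring probes and a loss of methylation on X, which would raise the same counts. The mean percent by rank did not pass its test (exact permutation p = 0.051, n = 4 and 16). A gain of methylation at these regions in carcinoma cells is a hypothesis that stays open, as does a different mix of cell types in the tissues, which was not tested because the regions have no gene names here.

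The input signal deviations of the carcinomas were weighed against dim signal and against slides. The 6 carcinomas with an input signal at least as bright as the dimmest normal gland had a median SD over autosomes of 0.0788, against at most 0.0139 in normal glands. This argues against dim signal as the whole cause of the chromosome values. Single windows were not checked in this way. Carcinomas on the same slide had more alike chromosome profiles than others by 0.167 in mean correlation (permutation p = 0.0836), so a part played by the slide could not be excluded or shown. Changes of DNA copy number in the carcinomas remain a hypothesis for the long runs.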

How the results depend on the processing

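The linear position, the log position, the percentile anchors, the single scan days, the share over 0.5, loess for the spread, the fit of the 8 samples without a block and the fits without chosen samples were added after seeing the data; the cause was not tested for any change below unless stated. Counts are of regions called in carcinomas. Higher calls in log2 ratio were 1576, and 471 after normexp, 2544 with array weights, 286 with a log2 difference of at least 1, 634 at an adjusted p under 0.01, 9090 of 91599 single probes, 3059 with percentile anchors, 609 in scan day 2 and 292 in scan day 3. Lower calls were 3216, and 1447 after loess, 1996 after quantile normalization, 22680 single probes, 589 in linear position, 573 in log position and 356 with percentile anchors. Lower calls made up 67.1% of calls, against 52.7% after loess, 86.1% after normexp, 20.1% in linear position, 22.9% in log position and 10.4% with percentile anchors. Higher calls in linear position were 2345, and 372 in scan day 2 and 462 in scan day 3; lower calls were 589, and 356 with percentile anchors, 14 in scan day 2 and 110 in scan day 3. Single scan days hold fewer samples. Leaving out each array in turn gave 891 to 2183 higher and 2842 to 3331 lower calls in log2 ratio, and 945 to 2743 higher and 164 to 650 lower in linear position. The lowest counts came without normal gland 1 (891, 2842, 945 and 164).

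The samples numbered 1 to 4 in both groups did not pair: same-numbered deviations correlated at 0.34, -0.29, 0.10 and -0.04. With the number as a replicate block, those 8 samples gave 1069 higher and 2668 lower regions, against 1443 and 2781 without it. Slide as a random block gave 1893 and 3363 (correlation -0.11), and in linear position 1975 and 436 in place of 2345 and 589 (correlation 0.0718).

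The difference in the share over 0.5 was 7.61 points in scan day 2 (exact permutation p = 0.0714) and 5.73 to 6.56 without each array. The chromosomes that differed numbered 11, and 6 after scaling by the median absolute deviation, 21 in linear position and 6 to 10 without each normal gland. The X mean differed by -1.71, by -1.92 to -1.36 without each normal gland, by -0.49 after quantile normalization and -1.09 after scaling by the median absolute deviation, and reversed to 0.0394 in linear position. The spread difference of 0.0549 was 0.0502 after loess, 0.0578 in linear position, 0.0644 in scan day 2 and 0.0463 in scan day 3, all no longer past the threshold, and 0.0485 to 0.0613 without each array. The median SD of log2 ratios, a different measure whose size cannot be set beside these, differed by 0.0600 and did not pass either. The input deviation difference of 0.0637 was 0.0617 in scan day 3 and 0.0525 to 0.0674 without each array. For the 10 named regions, 87 of the alternative values kept direction and call and 3 lost the call, but sizes moved. The 5 rises, 1.90 to 2.38, were 0.44 to 1.18 after normexp and 0.95 to 1.43 after loess. The 5 falls, -4.02 to -3.34, were -2.49 to -1.79 after normexp, -2.60 to -2.01 after quantile normalization and -1.54 to -0.42 after loess. GC corrections, genes, gene lists and probe classes were not run. Dim enriched signal limits regions of low ratio, and 7 regions had no probe well above background in Cy5 on any normal array.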

Other observations

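All tests in this part were chosen after the data had been seen. The higher calls in linear position lay near each other: 32.1% had a called neighbour within 100 kilobases, against a mean of 27.2% in 10000 random placements matched on mean position (permutation p = 0.0001, the smallest they can give). This was not particular to these calls: it was 20.6% against 14.4% for higher calls in log2 ratio (permutation p = 0.0001) and 9.51% against 6.78% for lower calls in linear position (permutation p = 0.0357). The megabases with most such calls were chosen after their values were seen. Chromosome 7 from 141000001 to 142000000 had 19 of 40 regions called, with a mean linear position of 0.117 in normal glands and 0.354 in carcinomas. Chromosome 4 from 80000001 to 81000000 had 18 of 28, from 0.151 to 0.474, and chromosome 3 from 57000001 to 58000000 had 13 of 20, from 0.199 to 0.564. Chromosome 7 from 10000001 to 11000000 also had 13 higher calls, of 76 regions, with 7 lower calls, and its mean was above every normal gland in 14 of 16 carcinomas. The megabase on chromosome 3 held the region with the largest rise in linear position, from 57274665 to 57274867, at 0.288 ± 0.129 (SD, n = 4) in normal glands and 1.13 ± 0.245 (SD, n = 16) in carcinomas, while its log2 ratio did not pass the test (difference -0.05, limma adjusted p = 0.920). In the megabases on chromosomes 3 and 4 and the one from 141000001 on chromosome 7, the mean of each of the 16 carcinomas was above every normal gland. A count of 19 was not beyond the random placements, whose 95th percentile for the fullest megabase was 20, while the highest percent of regions called in a megabase was 81.8, against a 95th percentile of 81.0.

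The carcinomas differed widely in how many regions low in normal glands had passed a linear position of 0.5. The share was 11.0% in carcinoma 15, 9.70% in carcinoma 8 and 7.92% in carcinoma 11, and 0.127% in carcinoma 2. Whether carcinomas with larger input deviations also had more regions in the upper part of the range was tested over the 16 carcinomas and not shown: Pearson r was 0.193 (permutation p = 0.480, adjusted p = 0.480) and Spearman rho was 0.271 (permutation p = 0.312, adjusted p = 0.312), with 2 relations tested. Without carcinomas 3 and 8, r was 0.661, so the pooled value depends on those samples. It was 0.744 in the 6 carcinomas of scan day 2 and -0.231 in the 8 of scan day 3. The upper mode and the share had r = -0.274 (permutation p = 0.303, adjusted p = 0.480) and rho = -0.312 (permutation p = 0.240, adjusted p = 0.312); r was -0.341 without carcinomas 7 and 10, -0.734 in scan day 2 and 0.0942 in scan day 3.

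In carcinoma 8 the input signal of X was lower over 165 megabases, with a mean of -0.55, while the median linear position of its X regions was 0.577, inside the range of 0.536 to 0.628 over all carcinomas. In 10 carcinomas with lower runs, the log2 ratio of autosomal regions inside them exceeded that outside by 0.01 to 0.27, and the linear position by 0.00186 to 0.0217.

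Other splits of the 20 arrays into 4 and 16 were fitted 100 times, the real split included. Of these, 1 gave as many higher calls in log2 ratio as the real split (1576, highest other 258), 1 as many lower calls (3216, highest other 2238) and 1 as many higher calls in linear position (2345, highest other 421). In each case this was the real split itself. With 100 of 4845 splits drawn, 1 in 100 is the lowest share possible. Chance is thus unlikely for these counts but not excluded. The real split also keeps each slide within 1 group, which other splits need not do. For lower calls in linear position, 3 splits gave at least the real 589. The others set carcinomas 6, 8, 11 and 15 (1259 lower) and carcinomas 7, 9, 11 and 15 (989 lower, 421 higher) against the rest. Both groups of 4 span scan days 2 and 3, and both hold carcinomas 11 and 15, which shared a slide. Carcinomas 6, 8, 11 and 15 had the highest shares of regions with a linear position over 0.5, from 21.3% to 25.4%, and 6 and 8 were on other slides. Their 1259 calls are regions higher in these 4 than in the rest, so they go with this structure among the carcinomas. A part played by the slide stays open for both groups. The share of such splits is under 0.05, but lower calls of this number also arose with no normal gland in the group of 4, so the count of 589 is not taken as specific to the difference from normal glands.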
